A study of Homo sapiens with 9 samples.

How the data were processed

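RNA sequencing was carried out on MDA-MB-231 cells held for 5 days in Matrigel, soft alginate or stiff alginate, with 3 libraries per matrix. Per the labels, the RNA was precipitated from lysates with ethanol and the libraries were made with a kit for low input, and the inhibitors, siRNA and paclitaxel that the same labels describe are assigned to none of the 9 libraries. Nothing in the sources used here says whether the libraries of a matrix came from separate cultures, so the p-values may measure technical spread. The deposited values are raw counts per gene, 1 column per library and 58684 genes, and none of the 9 columns was left out. The submitters' notes name FastQC, MultiQC, STAR, featureCounts of Subread, Seurat and DESeq2 without versions, and the genome builds hg38 and GRCh38.p10. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here.

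The deposited table also holds a gene length in bases. It equalled the whole span of the gene, introns included, for 32917 (89.0%) of the 36986 names found once in GENCODE 29, so reads were probably counted over gene bodies. Counts of genes that overlap, lie antisense to each other or have close paralogs or pseudogenes are uncertain for that reason. Positions are from GENCODE 29 on GRCh38. Depth is the total count per library, and levels are CPM, counts scaled to that total. A count of 0 was read as allowing up to 3 counts, which covers counting error only, since reads amplified by PCR are not independent molecules. Folds against a matrix with no count in any of its libraries were computed against 3 counts over the group.

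Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 9426, and libraries were scaled by TMM. All 9 libraries entered 1 quasi-likelihood fit with the matrix as the factor and robust estimation. The 3 contrasts were stiff against soft alginate, stiff alginate against Matrigel and soft alginate against Matrigel, each two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The labels pair no libraries. Genes changed in stiff alginate against both other matrices are calls of the same direction in both contrasts.

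Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided and adjusted over the lists, then with camera with an estimated correlation and with fry. Of 40 lists, 36 had at least 5 tested members. Levels of the marker lists of other cell types are given as summed CPM. Genes were named by a rule. It took FHL2 and CDKN1A. It took the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with at least 10 CPM in the higher group, no overlap between the groups' libraries and a symbol that is not a clone, antisense, LINC or pseudogene name. It took up to 4 members per list by adjusted p, with the best known members that did not pass where a level was needed, and up to 6 genes per direction for stiff alginate against both others. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

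The fixed alternatives were RLE and upper-quartile scaling, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, fits without robust estimation, fits of the 6 libraries compared, the replicate number as a block, mitochondrial and ribosomal protein genes left out, glmTreat against a fold of 1.5, and each library left out in turn. Those chosen after seeing the data were a filter of a mean of 100 CPM, limma-voom with group variances, the 6-library fit without stiff alginate library 1 and list tests on the 6 libraries compared.

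The pipeline was tested on simulated counts for 9426 genes, 200 of them changed by 2-fold, 4-fold or 8-fold. With each group's own spread, the fit of 9 libraries recovered 0%, 0% and 1.39% of them for stiff alginate against Matrigel with 0 false calls. It recovered 15.1%, 15.6% and 31.4% for stiff against soft alginate with 867 false calls, and 12.5%, 18.3% and 23.5% for soft alginate against Matrigel with 890. With the stiff alginate spread in every group it recovered 22.2%, 64.6% and 87.5% (3 false), 18.9%, 55.8% and 81.4% (2 false) and 29.2%, 61.7% and 82.4% (4 false) in the same order. The fit of the 6 libraries compared recovered 30.2%, 72.3% and 93.1% for stiff alginate against Matrigel with 1 false call and 0% at each fold for stiff against soft alginate. A list of cholesterol genes raised 2-fold ranked 1 among the lists (camera adjusted p = 3.23e-34), with 0 other lists called. The simulated genes were drawn independently of each other, so this result does not test the preset correlation. Simulations with no changed gene were run 20 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.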

Results

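Messenger RNA was measured in MDA-MB-231 cells, an established human line of triple-negative breast cancer, after 5 days inside a gel. The gel was either Matrigel, a basement membrane extract from a mouse tumour, or a soft or a stiff alginate hydrogel, a seaweed polysaccharide network joined by covalent bonds. Each of the 3 matrices had 3 libraries, 9 in all. The series title concerns a matrix that brings about dormancy, a resting state of tumour cells, and an axis of FHL2 and p21 that responds to stiffness. The comparisons below therefore set each alginate against Matrigel, and the stiff alginate against the soft one. Counts assigned to genes came to between 1539034 and 1946761 per library in Matrigel, between 1426575 and 1779463 in soft alginate and between 1364219 and 1810635 in stiff alginate.

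At these similar depths the soft alginate libraries held far fewer genes. Between 6644 and 7865 genes had at least 1 count in a soft alginate library, against 11806 to 13248 in stiff alginate and 13655 to 14247 in Matrigel. The soft alginate libraries also resembled each other less. The Spearman correlation across genes of log2 CPM (counts scaled to a common library total) between libraries of a group was 0.452 to 0.505 in soft alginate, 0.862 to 0.915 in stiff alginate and 0.965 to 0.969 in Matrigel. The biological coefficient of variation that edgeR estimated within a group was 181% in soft alginate, 38.5% in stiff alginate and 13.3% in Matrigel. Each comparison with soft alginate below rests on these uneven libraries. The nuclear-retained RNA MALAT1 stood at 15382 ± 2839 CPM in Matrigel and 60855 ± 4630.4 in stiff alginate (SD, n = 3), and it took 4.10% to 7.11% of the counts in the soft alginate libraries. Cytosolic ribosomal protein genes together gave 39732 ± 3090 CPM in Matrigel, 23937 ± 4640 in soft alginate and 27918 ± 3365 in stiff alginate. Mitochondrially encoded genes gave 59385 ± 4382, 92502 ± 16209 and 67767 ± 7678 CPM in the same order. Marker lists of other cell types were low or mixed. Fibroblast markers summed to 27.1 ± 1.49, 34.8 ± 55.1 and 34.7 ± 11 CPM, endothelial markers to 159.7 ± 14.0, 5.03 ± 5.02 and 25.4 ± 21.3, erythroid markers to 0.564 ± 0.0745, 4.56 ± 2.16 and 0.224 ± 0.389, leukocyte markers to 855 ± 42.1, 891 ± 424 and 459 ± 97.3, and keratins and other epithelial genes to 3647 ± 74.7, 2748 ± 305 and 3518 ± 345.

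**Figure D1:**
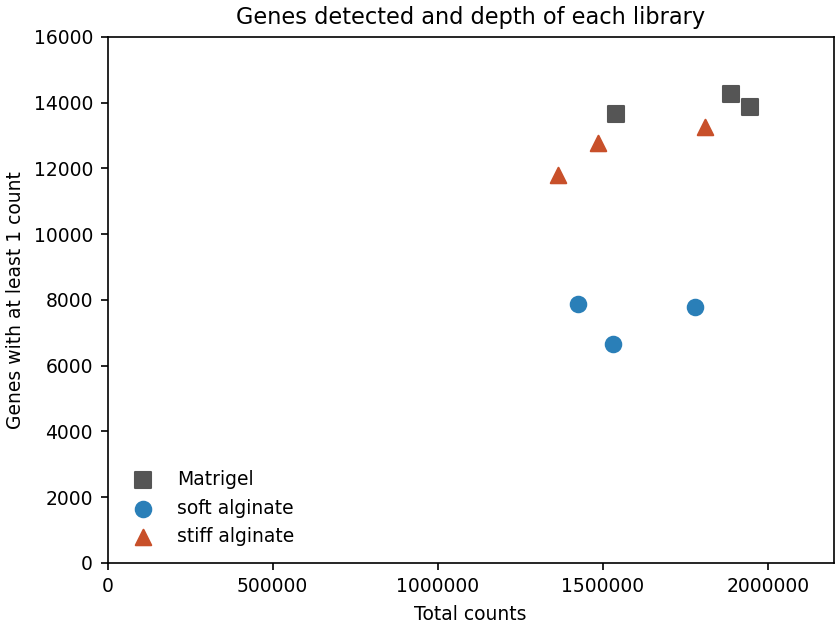
Number of genes with at least 1 count (vertical axis) against total counts (horizontal axis), 1 point per library, coloured by matrix. The 3 soft alginate libraries lie between 6644 and 7865 genes, below the 6 other libraries, which lie between 11806 and 14247 genes at similar depths.

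The title names FHL2 and p21, so these genes were read first. CDKN1A (chromosome 6, bases 36676460 to 36687339, plus strand, GRCh38) encodes p21, an inhibitor of the kinases that drive the cell cycle. It stood at 186 ± 16.9 CPM in Matrigel, 732 ± 211 in soft alginate and 691 ± 212 in stiff alginate (SD, n = 3 each). CDKN1A was 4.13-fold higher in soft alginate than in Matrigel (log2 fold change 2.05, SE 0.29, edgeR adjusted p = 0.00547) and 3.92-fold higher in stiff alginate than in Matrigel (1.97, SE 0.29, edgeR adjusted p = 0.0385). Between stiff and soft alginate its log2 fold change was -0.07 (SE 0.28, edgeR adjusted p = 0.968) and ranged from -0.26 to 0.19 over the alternatives. The stiff alginate call lay close to the threshold. It was lost when Matrigel library 1, 2 or 3 or stiff alginate library 2 or 3 was left out (edgeR adjusted p = 0.311, 0.323, 0.209, 0.222 and 0.238), and it was clearer when the 6 libraries compared were fitted alone (edgeR adjusted p = 0.00015). The soft alginate call was kept in each of the 6 fits that left out a library and was lost with limma-voom with group variances (adjusted p = 0.066).

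FHL2 (chromosome 2, bases 105357712 to 105438513, minus strand, GRCh38) encodes a LIM domain protein that binds integrins and transcription factors. Its level was 55.4 ± 2.22 CPM in Matrigel and 51.7 ± 13.6 in stiff alginate. In soft alginate FHL2 ranged widely, at 197.7, 82.9 and 0 CPM in the 3 libraries. For counting error alone a count of 0 allows up to 1.69 CPM, and molecules missed before sequencing would allow more. No difference in FHL2 passed the test. Its log2 fold change was -0.84 (SE 1.42, edgeR adjusted p = 0.90) for stiff against soft alginate, 0.82 (SE 1.42, adjusted p = 0.853) for soft alginate against Matrigel and -0.01 (SE 1.41, adjusted p = 1.00) for stiff alginate against Matrigel. The last value had an SE of 0.26 when the 6 libraries compared were fitted alone. None of the 3 differences kept its direction, with log2 fold changes over the alternatives of -1.41 to 1.95, -1.97 to 1.39 and -0.23 to 0.09 in the same order.

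**Figure D2:**
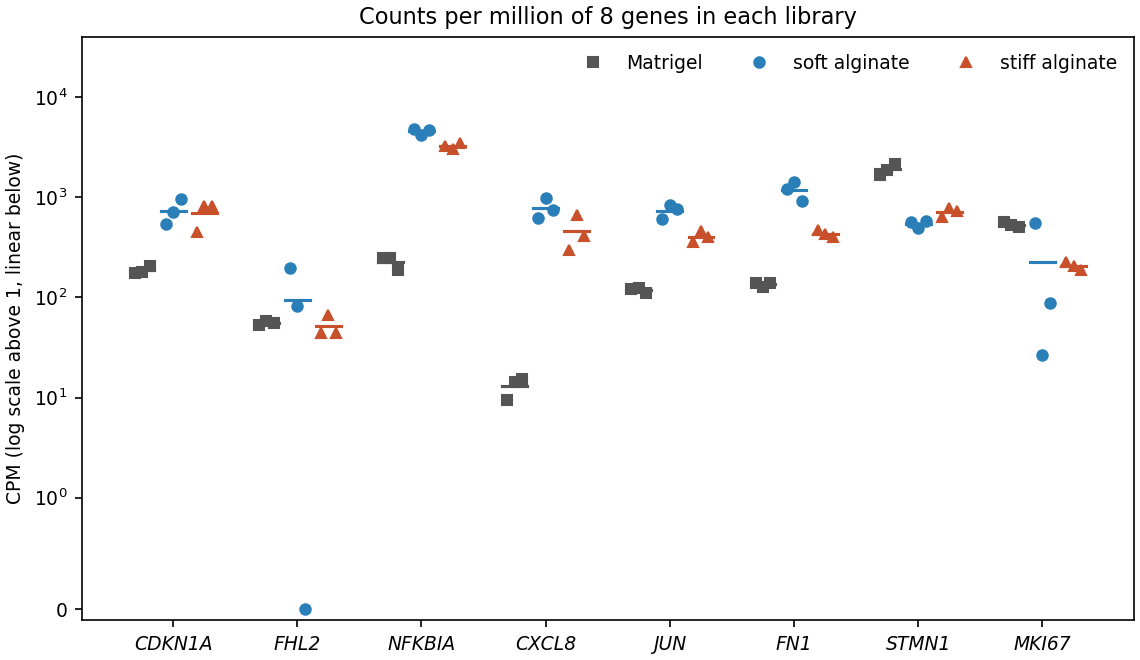
CPM (vertical axis, log scale above 1 and linear below) of 8 genes in each library, with squares for Matrigel, circles for soft alginate, triangles for stiff alginate and a bar at each group mean. CDKN1A, NFKBIA, CXCL8, JUN and FN1 lie higher in all 6 alginate libraries than in the 3 Matrigel libraries and STMN1 lies lower, while FHL2 and MKI67 spread widely among the soft alginate libraries.

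In stiff alginate against Matrigel neither group held the sparse libraries, but the fit of 9 libraries pooled their spread into this test too. It recovered 0%, 0% and 1.39% of simulated changes of 2-fold, 4-fold and 8-fold. A gene that did not pass is therefore not shown to be unchanged. Targets of NF-kB, the transcription factor family behind inflammatory gene expression, were higher in stiff alginate. Of the 21 members tested, 7 were higher and 0 lower, or 12 and 0 adjusted over the list alone, and the list passed camera (adjusted p = 3.5e-67, and adjusted p = 5.7e-05 with an estimated correlation). NFKBIA (chromosome 14, bases 35401511 to 35404749, minus strand), which encodes the inhibitor that holds NF-kB in the cytoplasm, rose 15.3-fold, from 226 ± 33.2 to 3249 ± 198 CPM (edgeR adjusted p = 9.6e-06). CXCL8 (chromosome 4, bases 73740506 to 73743716, plus strand), which encodes the neutrophil attractant interleukin-8, rose 36.6-fold, from 13.1 ± 3.13 to 455 ± 185 CPM (edgeR adjusted p = 0.000941). Its chromosome 4 neighbours CXCL1, CXCL2 and CXCL3 were 105-fold, 21-fold and 103-fold higher. The last 3 are near-identical in sequence, so how reads were divided among them is uncertain. TNFAIP3, which encodes a brake on NF-kB signalling, was 30.2-fold higher (edgeR adjusted p = 0.0224), and NFKBIZ was 8.11-fold higher (edgeR adjusted p = 0.0347). BIRC3, a target that inhibits apoptosis, stood at 290.1 ± 16.9 CPM against 66.6 ± 3.45 and did not pass (edgeR adjusted p = 0.0715). In the fit of the 6 libraries compared it passed (edgeR adjusted p = 9.9e-06), and 15 of the 21 members were higher and 0 lower. Secreted factors associated with senescence also rose (camera adjusted p = 5.7e-16, and adjusted p = 0.0055 with an estimated correlation), with 2 of 14 members higher. That list shares at least CXCL1, CXCL8, IL6 and ICAM1 with the NF-kB list, so the 2 results are not independent.

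Genes of mitosis and the G2/M phase were lower in stiff alginate than in Matrigel as a list (camera adjusted p = 4.0e-17, and adjusted p = 0.0056 with an estimated correlation). Together they gave 3702 ± 376 CPM in stiff alginate and 8978 ± 189 in Matrigel. Of the 39 members, 0 passed alone over all genes and 1 was lower adjusted over the list alone. In the fit of the 6 libraries compared, 27 of the 39 were lower and 0 higher. UBE2C, whose product marks cell cycle proteins for destruction, stood at 198 ± 16.4 CPM in stiff alginate and 461 ± 5.56 in Matrigel (edgeR adjusted p = 0.141, and 0.000486 in the 6-library fit). AURKA, a mitotic kinase, stood at 56.3 ± 9.90 and 214 ± 7.02 CPM (edgeR adjusted p = 0.996, and 0.000169 in the 6-library fit). MKI67, the proliferation marker Ki-67, stood at 206 ± 17.7 and 534 ± 30.9 CPM (edgeR adjusted p = 1.00, and 0.000246 in the 6-library fit). STMN1 (chromosome 1, bases 25884181 to 25906991), which encodes a protein that takes microtubules apart, was the 1 gene lower by the test over all genes, 2.51-fold, at 712 ± 67.9 against 1895 ± 255 CPM (edgeR adjusted p = 0.00995).

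Several further lists were higher in stiff alginate than in Matrigel. Lysosome and autophagy genes rose as a list (camera adjusted p = 1.1e-11, and adjusted p = 0.017 with an estimated correlation). Of the 26 members, 1 was higher, or 5 adjusted over the list alone, and in the 6-library fit 13 were. NPC2 (chromosome 14, bases 74476192 to 74494177), which carries cholesterol out of lysosomes, was 2.25-fold higher (edgeR adjusted p = 0.0266). CTSB, a lysosomal protease, stood at 785 ± 149 against 426 ± 18.7 CPM (edgeR adjusted p = 0.141, and 0.00261 in the 6-library fit). Genes of ERK signalling and immediate-early genes rose as a list (camera adjusted p = 0.0007, and adjusted p = 0.036 with an estimated correlation), with 2 of 23 members higher. The 2 members were JUN, a subunit of the transcription factor AP-1, at 3.64-fold (edgeR adjusted p = 0.00603), and IER3, also an NF-kB target, at 4.44-fold (edgeR adjusted p = 0.0228). In the 6-library fit that list kept the call with the preset correlation (adjusted p = 0.00913) and lost it with an estimated one (adjusted p = 0.106). Its members moved in both directions in that fit, with 5 of the 23 higher and 2 lower. The lower members were DUSP6 and EPHA2, with log2 fold changes of -1.02 and -1.03 (edgeR adjusted p = 0.0045 and 0.0184). The list of NRF2 and glutathione genes rose (camera adjusted p = 0.0005, and adjusted p = 0.036 with an estimated correlation), and its 2 of 20 higher members were FTH1 and FTL, the subunits of the iron store ferritin, at 2.37-fold and 1.78-fold. In the 6-library fit it too kept the call with the preset correlation (adjusted p = 0.00194) and lost it with an estimated one (adjusted p = 0.0899). Both ferritin genes have many pseudogenes, so their counts are uncertain. FN1 (chromosome 2, bases 215360440 to 215436172, minus strand), which encodes the matrix protein fibronectin, was 3.41-fold higher, at 432 ± 37.6 against 135 ± 7.47 CPM (edgeR adjusted p = 0.00774). INSIG1 (chromosome 7, bases 155297776 to 155310235), a sterol-responsive regulator of cholesterol synthesis, was 3.54-fold higher, at 959 ± 9.75 against 287.7 ± 48.0 CPM (edgeR adjusted p = 0.0069).

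Other lists passed camera with its preset correlation but lost the call when the correlation was estimated. YAP/TAZ targets, read as markers of mechanical signalling, were lower (adjusted p = 0.0126, and adjusted p = 0.152 with an estimated correlation), with 0 of 24 members past the test. CYR61, one of the best known of them, stood at 878 ± 282 CPM in stiff alginate and 2936 ± 74.0 in Matrigel (edgeR adjusted p = 0.785), CTGF at 233.5 ± 79.9 and 619 ± 3.43 (adjusted p = 1.00), and AXL at 526 ± 42.7 and 1133 ± 22.8 (adjusted p = 0.139). In the 6-library fit CYR61, CTGF, AXL and 1 other member were lower (edgeR adjusted p = 0.000239, 0.00415 and 0.000447 for the named genes) and 2 of the 24 were higher. The p53 target list was higher (adjusted p = 0.0114, and adjusted p = 0.143 with an estimated correlation), and CDKN1A was its 1 member past the test. In the 6-library fit 4 of its 21 members were higher and 0 lower. Beside CDKN1A these were PLK3, BBC3 and PMAIP1 (edgeR adjusted p = 0.0038, 0.00372 and 0.0355). With an estimated correlation the adjusted p was 0.0721 for the matrix genes, higher here, 0.0875 for cholesterol synthesis, higher, 0.104 for mesenchymal genes, higher, 0.124 for FOXO targets, higher, and 0.079 for ribosome biogenesis, lower. It was 0.141 for both glycolysis and DNA replication, each lower, 0.136 for cytosolic ribosomal proteins, lower, 0.354 for mitochondrially encoded genes, higher, and 0.130 for nuclear-retained RNAs, higher, where MALAT1 was the 1 member past the test, at 4.22-fold (edgeR adjusted p = 0.00891).

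Over all genes, 24 of the 9426 tested differed between stiff alginate and Matrigel, 23 higher and 1 lower (edgeR adjusted p below 0.05), and 288 had an unadjusted p below 0.05. The groups did not overlap for 29.9% of genes, against 10% by chance. This test pools the spread of all 9 libraries. The fit of the 6 libraries compared called 644 genes, 349 higher and 295 lower, including each of the 24, and DESeq2 over the 9 libraries called 101. The 24 fell to 4, 5 and 6 without Matrigel library 1, 2 or 3 and to 12, 7 and 8 without stiff alginate library 1, 2 or 3. NFKBIA, CXCL2, CXCL3 and CXCL8 passed in each of those 6 fits and TNFAIP3, NFKBIZ, IER3, STMN1, NPC2, FTL and MALAT1 in 0 of them. JUN lost its call without any 1 of the Matrigel libraries (adjusted p up to 0.0678), as did FN1 and FTH1, which also lost it without stiff alginate library 2 (up to 0.0834 for each), and FTH1 without stiff alginate library 3. INSIG1 lost it without Matrigel library 1 or 2 or stiff alginate library 2 or 3 (up to 0.0834) and CXCL1 without Matrigel library 1 (0.0627). IER3 and NPC2 were also lost with the replicate block, FTL with upper-quartile scaling and MALAT1 without a filter.

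Soft alginate against Matrigel showed many of the same named genes with larger fold changes, which were not tested against each other here except in the comparison of the alginates below. NF-kB targets were higher (camera adjusted p = 1.5e-25, and adjusted p = 0.00117 with an estimated correlation). Of the 21 members tested 10 were higher and 0 lower, or 12 and 0 adjusted over the list alone. NFKBIA rose 21.3-fold to 4584 ± 338 CPM (edgeR adjusted p = 4.3e-06) and CXCL8 rose 62.3-fold to 782 ± 190 CPM (edgeR adjusted p = 0.000314). CXCL1, CXCL2 and CXCL3 were 251-fold, 21.6-fold and 149.97-fold higher, with the same doubt about shared reads. TNFAIP3 was 65.6-fold higher, NFKBIZ 23.4-fold, IRAK2, an adaptor of interleukin-1 signalling, 26.9-fold, and BIRC3 5.94-fold (edgeR adjusted p = 0.00444, 0.00389, 0.00547 and 0.00547). Senescence-associated secreted factors rose as well (camera adjusted p = 8.5e-09, and adjusted p = 0.017 with an estimated correlation), with 7 of 14 members higher, or 8 adjusted over the list alone.

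Matrix genes were higher in soft alginate than in Matrigel (camera adjusted p = 3.4e-05, and adjusted p = 0.019 with an estimated correlation). Of the 30 members 4 were higher and 1 lower. FN1 rose 9.22-fold to 1185 ± 258 CPM (edgeR adjusted p = 0.000235) and COL6A1, a collagen chain, 2.50-fold (edgeR adjusted p = 0.0188). The list of ERK and immediate-early genes rose (camera adjusted p = 0.00014, and adjusted p = 0.026 with an estimated correlation), with 5 of 23 members higher and 2 lower. JUN was 6.53-fold, IER3 7.05-fold and KLF6, an immediate-early zinc-finger factor, 2.77-fold higher (edgeR adjusted p = 0.000354, 0.00389 and 0.00389). NRF2 and glutathione genes rose (camera adjusted p = 2.5e-06, and adjusted p = 0.017 with an estimated correlation), with 4 of 20 members higher. Among them FTH1 was 2.40-fold and NQO1, a quinone reductase, 1.89-fold higher (edgeR adjusted p = 0.0046 and 0.00547). CDKN1B, which encodes the cell cycle inhibitor p27, was 6.63-fold higher (edgeR adjusted p = 0.0158), PLK3, a stress-responsive kinase, 8.43-fold (edgeR adjusted p = 0.00625), and INSIG1 3.36-fold (edgeR adjusted p = 0.00427). Lysosome genes passed camera with the preset correlation (adjusted p = 0.000903) and not with an estimated one (adjusted p = 0.118), with 5 of 26 higher and 2 lower. CTSB was 2.83-fold and SQSTM1, an autophagy receptor, 3.51-fold higher.

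Mitosis genes were lower in soft alginate than in Matrigel (camera adjusted p = 7.4e-09, and adjusted p = 0.030 with an estimated correlation), with 18 of 39 members lower and 0 higher, and 28 of the 39 had no count in at least 1 library. UBE2C fell 4.34-fold, to 101.3 ± 13.2 CPM, and STMN1 fell 3.31-fold, to 545 ± 43.4 CPM (edgeR adjusted p = 0.00389 and 0.00177). CDCA8, CCNB2 and NDC80, which act in chromosome segregation and mitotic entry, had no count in any soft alginate library. Against a floor of 3 counts over the group they were 249.7-fold, 186-fold and 173-fold lower (edgeR adjusted p = 0.00547 each). That floor covers counting error only, so these folds are no lower bounds where the soft alginate libraries missed molecules. RUVBL1 and PRCC, also at 0 in all 3 libraries, were 187-fold and 176-fold lower against the same floor. MKI67 did not pass (edgeR adjusted p = 0.520), and its 3 soft alginate libraries lay at 556, 26.8 and 88.8 CPM. Without soft alginate library 1 it was lower (edgeR adjusted p = 0.00376). AXL, a receptor tyrosine kinase and YAP/TAZ target, fell 2.91-fold and F3, which encodes tissue factor, fell 3.76-fold (edgeR adjusted p = 0.00547 each), while the YAP/TAZ list did not pass camera (adjusted p = 0.708), with 5 of 24 members lower and 2 higher. NPM1 and NCL, nucleolar proteins of ribosome assembly, fell 1.87-fold and 2.87-fold, and GAPDH fell 1.70-fold (edgeR adjusted p = 0.009, 0.00868 and 0.00547). DNA replication genes were lower (camera adjusted p = 0.0416, and adjusted p = 0.400 with an estimated correlation), and mitochondrially encoded genes, integrins, nuclear-retained RNAs and ATF4 targets were higher with adjusted p = 0.118, 0.121, 0.343 and 0.114 with an estimated correlation. The mean log2 fold change of the ATF4 list lay below 0 while its median and its test pointed up.

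Over all genes, 1648 differed between soft alginate and Matrigel, 174 higher and 1474 lower (edgeR adjusted p below 0.05), around a median log2 fold change of -0.31 over all genes. Of the 1474 lower genes 952 had no count in any soft alginate library. In 20 simulations with no changed gene and each group's own spread, the same test called a median of 59 genes higher and 778 lower. With limma-voom with sample quality weights 39 genes passed, 38 higher and 1 lower, and with group variances 29 higher and 0 lower. NFKBIA, CXCL1, CXCL2, CXCL3, CXCL8, TNFAIP3, NFKBIZ, FN1, JUN, IER3 and KLF6 passed in each of these fits and in each fit that left out a library. The count rose to 3171, 2938 and 2901 without soft alginate library 1, 2 or 3. COL6A1 and CDKN1B lost their calls without any 1 of the Matrigel libraries (adjusted p up to 0.0854 and 0.0855), with the replicate block and, for COL6A1, in the 6-library fit and, for CDKN1B, without a filter. STMN1, UBE2C, AXL, F3, GAPDH, NPM1, NCL, NQO1, COL6A1, CDKN1B and the 5 genes at 0 were lost in both limma-voom fits, and CTSB and INSIG1 in the fit with group variances.

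**Figure D3:**
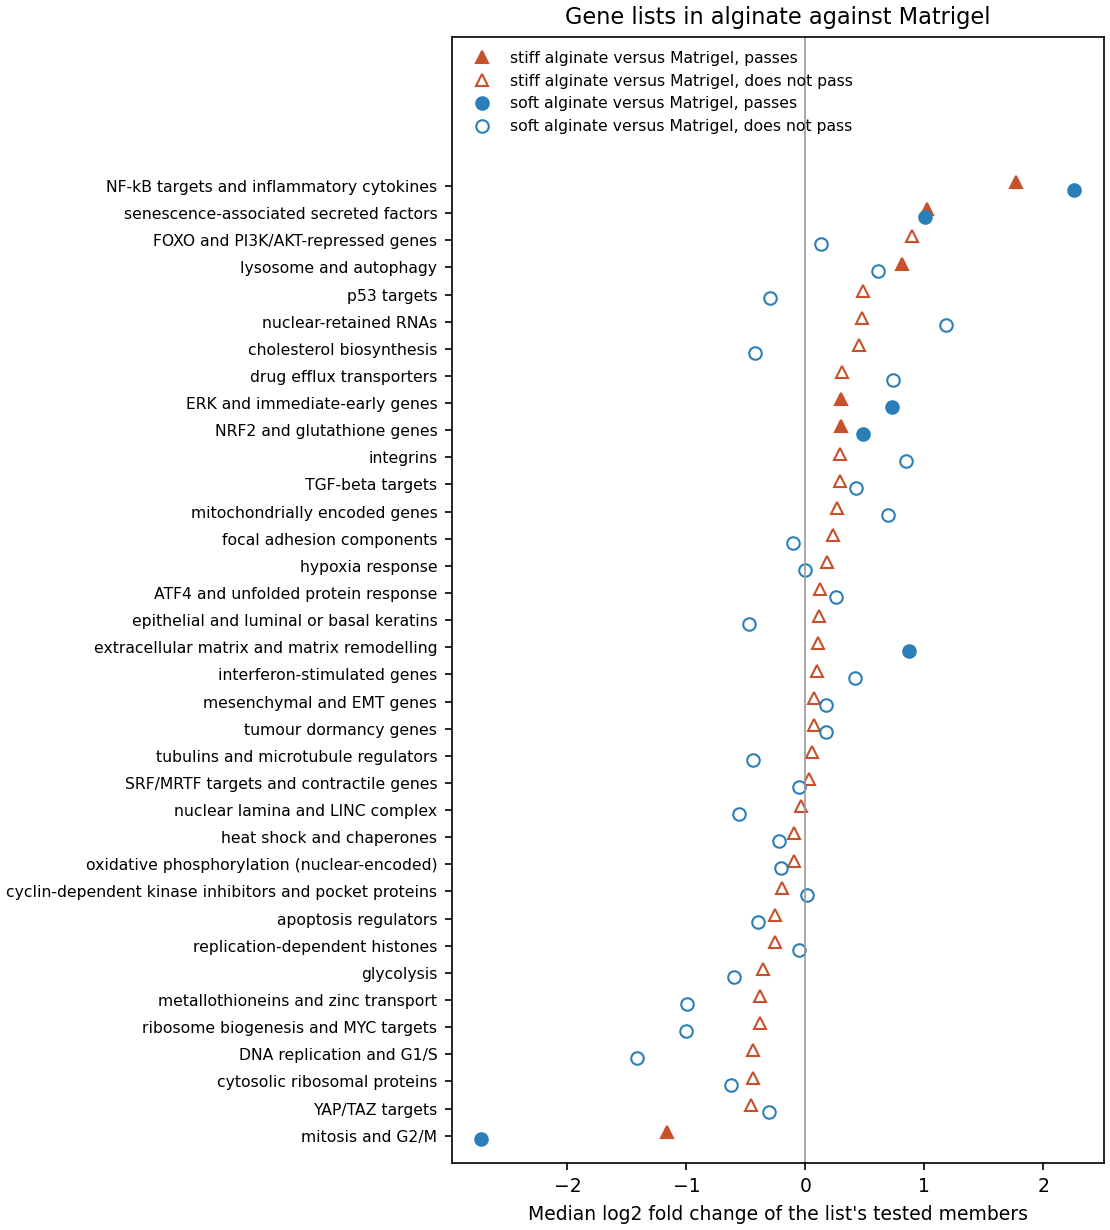
Median log2 fold change of the tested members of each gene list (horizontal axis), with triangles for stiff alginate and circles for soft alginate, each against Matrigel. Filled symbols passed camera with an estimated correlation, among them the NF-kB list at 1.77 and 2.26 and the mitosis list at -1.16 and -2.72. Genes without a count in any soft alginate library were also set at their floor, and the difference in median was 0 for each list. That swap replaces a large fold with another large fold and leaves genes missed in only some libraries as they are. It therefore cannot tell whether missed counts moved the medians.

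The same calls in both alginates were counted directly. Of the 23 genes higher in stiff alginate than in Matrigel, 23 were also higher in soft alginate, where independent lists would share 0.425, and the 1 lower gene, STMN1, was lower in both, where independent lists would share 0.156. Both comparisons use the same Matrigel libraries. Across the 9426 genes the covariance of the log2 fold changes was 0.545, against at most 0.0602 in simulations with no changed gene, which shared their Matrigel libraries in the same way, and the correlation across genes, which are not independent replicates, was 0.269. Those simulations held no shift in library make-up common to both alginates, such as the higher MALAT1 and lower ribosomal protein counts seen here. The covariance therefore does not separate such a shift from a shared response of the cells.

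Stiff against soft alginate addresses stiffness within one gel chemistry. The test called 37 genes lower in stiff alginate, where 20 simulations with no changed gene and each group's own spread called 38 to 80. Calls in that direction were thus no more numerous than unequal spread alone gave. Among abundant genes with counts in all 6 libraries, FN1 was 2.70-fold lower in stiff alginate, at 432 ± 37.6 against 1185 ± 258 CPM (edgeR adjusted p = 0.00623), IGFBP7, a secreted factor of the senescence list, was 2.07-fold lower (edgeR adjusted p = 0.00772) and TAGLN2, which encodes the actin-binding protein transgelin-2, was 1.66-fold lower (edgeR adjusted p = 0.00679). JUN, KLF6 and NFKBIA were 1.79-fold, 1.56-fold and 1.39-fold lower (edgeR adjusted p = 0.0134, 0.0214 and 0.042), and CXCL8 did not pass, at 455 ± 185 against 782 ± 190 CPM (edgeR adjusted p = 0.20). Under the naming rule the 3 genes lower in stiff alginate by the largest fold were RRAGB, NSUN6 and WDR62, at 11.6-fold, 10.4-fold and 7.15-fold (edgeR adjusted p = 0.0496, 0.0384 and 0.0354), each lost without any 1 of the stiff alginate libraries (adjusted p up to 0.143, 0.132 and 0.131). After them came ANTXR1, an anthrax toxin receptor that binds matrix, at 6.68-fold, COL8A1, a collagen chain, at 5.25-fold, FUCA1, a lysosomal fucosidase, at 3.93-fold, DPYD at 3.50-fold and DOCK9 at 3.39-fold. COL8A1 stood at 308 ± 304 CPM in soft alginate, a spread as wide as its mean. Over the alternatives the log2 fold change ranged from -2.80 to -1.15 for COL8A1 and from -3.21 to -1.77 for WDR62.

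Higher in stiff than in soft alginate were DUSP4, a phosphatase that limits ERK signalling, at 3.48-fold, with 397 ± 12.1 against 116 ± 32.3 CPM, and F3 at 3.37-fold, with 387 ± 25.8 against 115.8 ± 40.6 CPM (edgeR adjusted p = 0.00623 each). CCND1, encoding cyclin D1, and ITGA3, an integrin chain, were each 1.60-fold higher (edgeR adjusted p = 0.0233 and 0.0272), HK1, a hexokinase, was 2.49-fold higher and GNL3, a nucleolar protein, 5.48-fold higher (edgeR adjusted p = 0.0191 and 0.0108). PRCC, FDX1, MTF2 and DIAPH3 had no count in any soft alginate library. Against a floor of 3 counts over the group they were 155.9-fold, 152-fold, 121-fold and 112-fold higher. These folds too are no lower bounds where molecules were missed. CDCA8 of mitosis and TYMS of DNA replication, likewise at 0, were 87.1-fold and 46.1-fold higher against the same floor. MKI67 and CYR61 did not pass (edgeR adjusted p = 0.989 and 0.680), but MKI67 was higher in stiff alginate when soft alginate library 1 was left out (edgeR adjusted p = 0.0239) and CYR61 likewise when soft alginate library 3 was (edgeR adjusted p = 0.00595).

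No list call between stiff and soft alginate held with an estimated correlation. With the preset correlation mitosis genes were higher in stiff alginate (camera adjusted p = 0.00185, and adjusted p = 0.204 with an estimated correlation), with 8 of 39 members higher. NF-kB targets were lower (camera adjusted p = 0.00019, and adjusted p = 0.0905 with an estimated correlation), with 1 of 21 members higher and 1 lower. Matrix genes and NRF2 genes were lower, with the same adjusted p of 0.0905 with an estimated correlation, as were ERK and immediate-early genes (adjusted p = 0.129 with an estimated correlation), senescence factors and ATF4 targets (adjusted p = 0.143 each), mitochondrially encoded genes (adjusted p = 0.207) and nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.575). For the ATF4 list the mean log2 fold change was above 0 while its median and test pointed down, and for oxidative phosphorylation both the mean and the median were above 0, so those tests speak of a position relative to the other genes.

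Over all genes, 1335 differed between stiff and soft alginate, 1298 higher and 37 lower (edgeR adjusted p below 0.05), around a median log2 fold change of 0.29 over all genes. Of the 1298 higher genes 869 had no count in any soft alginate library and 1244 had none in at least 1. The simulations with no changed gene and each group's own spread gave a median of 859 calls, between 711 and 943. The median was 799 for higher calls and 59 for lower calls, the latter between 38 and 80. A median of 378.5 higher calls, 336 to 422, fell on genes without a count in any soft alginate library. In the edgeR fit of 9 libraries 2024 genes had an unadjusted p below 0.05. The fit of the 6 libraries compared and both limma-voom fits called 0 genes, and DESeq2 called 2013. The count rose to 2753, 2465 and 2538 without soft alginate library 1, 2 or 3. FN1, DUSP4, F3, IGFBP7 and TAGLN2 passed in each of the 6 edgeR fits that left out a library. So did PRCC, FDX1, MTF2, DIAPH3, CDCA8 and TYMS, which had no count in any soft alginate library. Those fits keep the unequal spread, so passing them does not separate a change from it. KLF6, ITGA3, DPYD and FUCA1 lost their calls without any 1 of the stiff alginate libraries (adjusted p up to 0.0946, 0.0733, 0.154 and 0.069), as did NFKBIA, also without soft alginate library 1 or 3 (up to 0.169), and COL8A1, also without soft alginate library 3 (up to 0.171). CCND1 and ANTXR1 lost theirs without stiff alginate library 2 or 3 (up to 0.0623 and 0.106), HK1 without stiff alginate library 2 (0.0812) and JUN without stiff alginate library 3 (0.059). Other settings ended calls too. Upper-quartile scaling ended those of KLF6, NFKBIA, DPYD, COL8A1 and RRAGB, RLE size factors those of ITGA3 and CCND1, no filter those of ITGA3, ANTXR1, DOCK9, DPYD, HK1, RRAGB, NSUN6 and WDR62, the stricter filter those of NFKBIA, COL8A1 and RRAGB, and leaving out mitochondrial and ribosomal protein genes that of RRAGB. The replicate block ended those of KLF6, NFKBIA, ITGA3, CCND1, ANTXR1, DOCK9, DPYD, COL8A1, HK1, RRAGB, NSUN6 and WDR62, and the filter at a mean of 100 CPM ended those of F3, JUN, KLF6, NFKBIA, IGFBP7, TAGLN2, ITGA3, CCND1, DOCK9, COL8A1, FUCA1, HK1 and GNL3.

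One gene, NPC2, was higher in stiff alginate than in both other matrices and 0 genes were lower, where independent lists would share 3.17 and 0.00393. Both comparisons use the same stiff alginate libraries, so independent lists do not give the value without change. Each of the 20 simulations with no changed gene gave 0 such genes. They also called 0 genes for stiff alginate against Matrigel, so this overlap could only be 0. It therefore cannot tell whether 1 shared gene is more than chance. NPC2 stood at 921 ± 60.7 CPM in stiff alginate, 622 ± 86.1 in soft alginate and 435 ± 43.6 in Matrigel (edgeR adjusted p = 0.0369 against soft alginate and 0.0266 against Matrigel). That count was 0 when Matrigel library 1, 2 or 3 or stiff alginate library 1, 2 or 3 was left out and 2 without soft alginate library 2. NPC2 also lost its call against soft alginate with RLE size factors and without a filter.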

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

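The filter at a mean of 100 CPM, limma-voom with group variances, the 6-library fit without stiff alginate library 1 and the list tests on 6 libraries were chosen after seeing the data. Where no reason is given, the cause was not tested. The 1335 genes of stiff against soft alginate were 2013 with DESeq2 (1708 higher, 305 lower), 848 with the replicate block, 3 with the filter at 100 CPM (2068 genes tested) and 0 with limma-voom with sample quality weights, with group variances and in the 6-library fit, and 1157 to 2753 with a library left out. The 24 genes of stiff alginate against Matrigel were 101 with DESeq2, 887 with limma-voom with sample quality weights, 657 with group variances, 644 in the 6-library fit, 1304 there without stiff alginate library 1, 38 with the filter at 100 CPM and 11 against a fold of 1.5, a stricter test by construction, and 4 to 12 with a library left out. The 6-library fit and both limma-voom fits called each of the 24. The 1648 genes of soft alginate against Matrigel were 39 with limma-voom with sample quality weights, 29 with group variances, 195 with the filter at 100 CPM (137 higher, 58 lower) and 1197 to 3171 with a library left out. The 1 gene of stiff alginate against both others was 9 with DESeq2, 0 with RLE size factors, limma-voom with sample quality weights or group variances, the 6-library fit, the replicate block, the fold of 1.5 and the filter at 100 CPM, and 0 to 2 with a library left out. RLE and upper-quartile scaling, both count filters fixed beforehand, fits without robust estimation and fits without mitochondrial and ribosomal protein genes left the other 3 counts within 1.5 times. CDKN1A in stiff alginate against Matrigel had log2 fold changes of 1.84 to 2.19 with a library left out (adjusted p 0.0453 to 0.323), and in soft alginate against Matrigel 2.03 with limma-voom with group variances (adjusted p = 0.066). No FHL2 difference passed under any alternative. MKI67 in stiff against soft alginate ranged from -0.62 to 1.84 with a library left out and passed at 1.84, without soft alginate library 1 (adjusted p = 0.0239).

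Same-number libraries of different matrices had correlations of their deviations, across genes, between -0.068 and 0.0785, so the numbers showed no pairing, and the block is a check only. Pairs of libraries differed by more than counting error, with chi-square per degree of freedom between 2.51 and 102.4, which does not show that they came from separate lysates. Among named genes other than FHL2 and CDKN1A, 1647 of 2085 alternative values stayed on their side of the threshold, 4 of them with the direction turned and no call in either setting, 303 lost the call, 134 gained it and 1 reversed with a call. For FHL2 and CDKN1A 14 of 107 values turned in direction with no call in either setting. Among list values 1170 of 1296 stayed on their side, 47 of them with the direction turned and no call in either setting, 67 lost the call, 29 gained it and 30 reversed with a call in at least 1 setting. List calls went from 9 to 0 with an estimated correlation, 23 with fry and 5 to 10 with a library left out for stiff against soft alginate. They went from 18 to 6, 9 and 16 to 20 for stiff alginate against Matrigel, and from 12 to 6, 26 and 9 to 13 for soft alginate against Matrigel. The median, mean and camera direction of a list differed in sign for 23, 3 and 18 of the 36 lists in that order, 2, 0 and 1 of them called.

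The 30 reversals with a call, and 13 of the 47 turns without one, came with fry, which tests the members' own movement where camera sets them against other genes. The median log2 fold change over all genes was 0.29 for stiff against soft alginate and -0.31 for soft alginate against Matrigel. In stiff against soft alginate 12 of 21 p53 members, 11 of 17 FOXO members and 10 of 23 dormancy members had no count in at least 1 library. The fry directions below therefore do not separate missed counts in soft alginate from a change of the list. In stiff against soft alginate fry pointed up for the lists of p53 (adjusted p = 0.015), YAP/TAZ (0.0124), SRF/MRTF (0.0215), focal adhesion (0.00103), nuclear lamina (0.0423), oxidative phosphorylation (0.312), ATF4 (0.0306), heat shock (0.0075), ERK (0.557), FOXO (0.0206), TGF-beta (0.00222), interferon (0.00945), dormancy (0.0286), tubulins (0.00359), drug efflux (0.0189), apoptosis (0.00737) and lysosome (0.0209). In soft alginate against Matrigel it pointed down for cyclin-dependent kinase inhibitors (0.012), SRF/MRTF (0.0404), focal adhesion (0.00139), nuclear lamina (0.00866), cholesterol synthesis (0.00016), ATF4 (0.0535), heat shock (0.00754), TGF-beta (0.0148), interferon (0.012), dormancy (0.0335), tubulins (0.0022), drug efflux (0.0491) and apoptosis (0.00976).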

Other observations

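Some lists chosen for a dormant or drug-tolerant state did not pass camera between stiff alginate and Matrigel, and single members stood apart in the fit of the 6 libraries compared. The list of tumour dormancy genes had an adjusted p of 0.916, with 0 of 23 members past the test in the 9-library fit. Its members BHLHE40, a circadian and stress-responsive repressor, and DDR1, a collagen receptor, stood at 111 ± 38.0 and 127 ± 26.1 CPM in stiff alginate against 52.5 ± 5.13 and 53.4 ± 2.10 in Matrigel (SD, n = 3; edgeR adjusted p = 0.0224 and 0.00419 in the 6-library fit, 1.00 each in the 9-library fit), while AXL, also on that list, was 2.03-fold lower (edgeR adjusted p = 0.000447 in the 6-library fit). Drug efflux transporters had an adjusted p of 0.569, and ABCC3, which exports conjugated drugs and bile salts, stood at 371 ± 93.6 against 134 ± 25 CPM (edgeR adjusted p = 0.00105 in the 6-library fit, 1.00 in the 9-library fit). Among cyclin-dependent kinase inhibitors (list adjusted p = 0.662), CDKN2C, which encodes p18, stood at 26.6 ± 6.21 against 95.8 ± 5.10 CPM (edgeR adjusted p = 0.00172 and 1.00 in the same order), the opposite direction to CDKN1A.

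Lists of attachment and contraction did not pass either, with camera adjusted p of 0.0564 for integrins, 0.370 for focal adhesions, 0.421 for SRF/MRTF targets, 0.262 for the nuclear lamina and 0.0721 for TGF-beta targets, which passed fry in the direction of higher expression (adjusted p = 0.0155). ITGAV, an integrin chain, stood at 16.3 ± 5.38 CPM in stiff alginate against 2.22 ± 0.376 in Matrigel, MYH9, non-muscle myosin, at 996 ± 82.2 against 682 ± 26.1, and CAV1, caveolin-1, at 811 ± 73.7 against 1312 ± 30.2 (edgeR adjusted p = 0.0129, 0.00972 and 0.0148 in the 6-library fit, 1.00, 0.160 and 0.488 in the 9-library fit). Interferon-stimulated genes had an adjusted p of 0.544, with IFI27 at 529 ± 83.6 against 227 ± 11.4 CPM (edgeR adjusted p = 0.000387 and 0.0633 in the same order) and IFITM2 at 60.7 ± 10.99 against 114 ± 15.0 (edgeR adjusted p = 0.049 and 1.00). The adjusted p was 0.916 for hypoxia, heat shock and replication-dependent histones, 0.712 for ATF4 targets, 0.376 for apoptosis regulators, 0.227 for oxidative phosphorylation, 0.344 for metallothioneins, 0.972 for tubulins and 0.529 for keratins.

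Of the tests below, those of NF-kB targets and of genes missed in the soft alginate libraries at random were chosen after the results were seen. With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split was 1 of the 10 with as many genes in each comparison, with 1335, 24 and 1648 genes for stiff against soft alginate, stiff alginate against Matrigel and soft alginate against Matrigel, and the highest other split gave 0 each time.

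The soft alginate libraries held few genes, and most calls against them were genes without a count there. Genes seen in exactly 1 soft alginate library, 4061 of them, had a median of 9 counts there and an upper quartile of 58, against medians of 1 in both other matrices, so few captured RNA molecules may be a cause, but 9 lay between the bounds of 10 and 3 set for and against it. Unequal spread between the groups gave a median of 859 calls in simulations with no changed gene, against 1335 real ones, although those simulations had a median of 441 genes at 0 in all 3 soft alginate libraries and the data had 999. Misses at random in each library, at the rate of genes of like abundance, would give 739 such genes, a ratio of 1.35 that leaves room for losses shared by the libraries or lower expression. Lower expression stayed open as well, since the summed CPM of 6256 genes of middle abundance in soft alginate reached 1.046 of the stiff alginate mean (0.951 and 0.996 in the other libraries), but losing the 599 called genes among them would lower it by only 5.42%, so the bound of 0.9 set beforehand was wrong.

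NF-kB targets were higher in both alginates. Of the 21 members tested, 10 had all 6 alginate libraries above all 3 Matrigel libraries, where chance gives 1.19% of genes and 2.11% of all genes tested did so, and 10000 random lists of like expression had a median of 1 and at most 6. The 10 members exceeded every random list, but a first bound of 11 members was missed by 1. The test was also set after the members were seen to be higher in these data. Random lists do not share regulation by NF-kB, so these values do not decide whether amplification noise contributed. A stress response to retrieval from the gel may be a source and stayed open. The heat shock list had a median log2 fold change of -0.096 with members in both directions. The immediate-early list was higher as a list, with 5 of its 23 members higher and 2 lower in the 6-library fit. The matrix itself stayed open too, and nothing here separates alginate from the handling it needs.

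Nuclear-retained RNA was higher and ribosomal protein messages were lower in stiff alginate than in Matrigel by camera with the preset correlation alone. NEAT1 stood at 2993 ± 280 against 600 ± 127 CPM (edgeR adjusted p = 4.1e-06 in the 6-library fit, 0.233 in the 9-library fit). More nuclear or intronic RNA among the counted reads may be a source, and the log2 fold change rose with gene span across genes, which are not independent replicates, with a Spearman rho of 0.167, between the bounds of 0.2 and 0.05 set for and against it, and of 0.214 for soft alginate against Matrigel among 2068 genes with a mean of at least 100 CPM. In groups of rising span the medians were -0.10, -0.06, 0.02 and 0.20. A change in transcription of these genes was not tested and stayed open.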
